A study of Homo sapiens with 30 samples.

How the data were processed

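The deposited values were a matrix of intensity values, 1 per probe set, for 54675 probe sets on 30 arrays, and each array was a column of it. Total RNA was extracted with Trizol LS and turned into biotin-labelled cRNA by in vitro transcription, per the labels' protocols. The submitters' processing notes name MAS5 and RMA. Their versions, and which of them made the values used here, are not given in the sources used here. The values themselves were linear intensities, all above 0, with 21.61 to 22.82% of the probe sets of an array under 16. No log transformation and no centring of genes was seen in them. The scanner files were not used here.

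Each value was turned into log2(value + 16), with no further normalization. Probe sets were named from a table of the platform's annotation: 41097 carried 1 gene symbol, 1801 several, and 11777 none in the table given. Of the single-symbol probe sets, 41043 were matched to a table of human genes by gene identifier, and 0 symbols needed an update. Probe sets with several symbols or none were left out. A gene was represented by the probe set with the highest mean over the 30 arrays, and it was tested if that probe set lay above its array's median on at least 2 arrays. Of 19775 genes with a probe set, 15055 were tested, and 9341 of these had more than 1 probe set. The other probe sets of each named gene were checked for direction.

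Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 1 mean for each of the 14 groups of arrays, so that all groups shared 1 estimate of the spread. All tests were two-sided, with Benjamini-Hochberg adjustment over the 15055 genes and a threshold of 0.05. AR341787 had 1 array in each of 2 lines. It was therefore fitted on the 14 arrays of those lines with a term for the line, so that the difference between its 2 arrays counted toward the spread. The same limma fits tested 17 gene lists with camera, with a preset correlation between genes of 0.01 and adjustment over the lists within a comparison. Each list test was repeated with a correlation estimated from the data. Of the 76 list calls over all comparisons, 2 held with the estimated correlation: the ERK pathway list for arrays labelled A375control_1677 and for arrays labelled A375sh2BRaf_B439006. Tables were handled with data.table (1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

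The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule names, for each comparison, the 6 genes with the highest and the 6 with the lowest log2 fold change among those past the threshold whose treated arrays all lay outside the range of the control arrays on the same side. For interactions, direct differences of compounds, the vehicle check and doxycycline in shGFP it names 3 and 3. It also names up to 3 past-threshold members of each list, those with the smallest p, and 7 genes always: DUSP6, SPRY4, ETV5, CCND1, MITF, CDKN1B and CYP1A1. Genes of probe sets with several symbols or none are not named, nor are genes of the Y chromosome. The text gives a part of the genes so chosen. The rule also asked for the gene that the hairpins target, but the probe table used here names no probe set for it, so its level is not analysed here.

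The lists cover ERK pathway output and feedback, the RAS-RAF-MEK-ERK components, DNA replication, mitosis, cell cycle inhibitors, the melanocyte lineage, receptor tyrosine kinases, invasion and matrix, the BCL2 family, p53 targets, cholesterol biosynthesis, glycolysis, ribosome biogenesis, the integrated stress response, the interferon response, aryl hydrocarbon receptor targets and markers of other cell types. Members without a named probe set or under the intensity filter were not tested, and 9 of 14 pathway components and 5 of 12 markers of other cell types were.

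The fits were tested on simulated data with 200 of the 15055 genes changed. For doxycycline in shBRaf, 16.0% of the genes changed by 0.5 log2 units were recovered, 67.5% of those changed by 1 and 91.5% of those changed by 2. The shares were 14.5, 59.0 and 86.5% for doxycycline in sh2BRaf, 10.5, 49.5 and 80.0% for the difference between shBRaf and shGFP, and 11.0, 70.5 and 89.5% for AR341787. Between 0 and 16 unchanged genes were called. The simulated values varied independently between genes and arrays, with no effect of the replicate number and no array standing apart. These shares and counts therefore need not hold for the real arrays. Columns were checked for copies, and 0 pairs of arrays held identical values. Alternatives tried were quantile normalization, centring each array on its median, pseudocounts of 1 and 64, no intensity filter, a filter at the 60th percentile, the mean of all probe sets of a gene, every probe set on its own, only the groups compared in the fit, eBayes without the trend, the replicate number as a block, a minimum log2 change of 1, an estimated correlation in camera, and leaving out each array in turn. The number of arrays in each group, from 1 to 3, limits the precision.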

Results

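Expression was measured on Affymetrix HG-U133 Plus 2.0 arrays, which carry short probes for transcripts of most human genes. All 30 arrays held RNA of A375, a human melanoma cell line that depends on the RAF-MEK-ERK kinase cascade, and the series title asks about a RAF kinase inhibitor. The labels name 4 derived lines. A375control gave 6 arrays: 2 with the vehicle DMSO (A375control_DMSO) and 2 with each of a pair of compounds at 10 µM, named by their codes in the groups A375control_1677 and A375control_B439006. The line A375sh2BRaf (sh2BRaf below) gave 10 arrays: 2 each for Control, doxycycline (Dox), DMSO and the same pair of codes (A375sh2BRaf_1677 and A375sh2BRaf_B439006). The lines A375shGFP and A375shBRaf (shGFP and shBRaf below) gave 7 arrays each: 3 Control, 3 Dox and 1 with the compound labelled AR341787. Doxycycline was given for 48 h to induce a short hairpin RNA, and AR341787 was given at 1000 nM for 24 h. The doses of that pair in sh2BRaf are not given in the sources used here. The gene that the hairpins target was not analysed here, so the knockdown itself has no value, and groups are named by their labels.

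The arrays had median intensities of 68.65 to 73.4 and upper quartiles of 342.2 to 369.7. The highest intensity of an array lay between 20667 and 35626, with a median of 31081. Correlations between replicate arrays across probe sets ran from 0.947 to 0.986. The ratio of the 3′ to the 5′ probe sets, which rises as RNA breaks down, was 0.862 to 1.23 for GAPDH and 1.085 to 2.227 for ACTB. The spread between arrays of 1 group may be technical, since the labels do not say whether replicates were separate cultures. In what follows, changes are log2 fold changes with their standard errors (SE), intensities are means with standard deviations (SD), and adjusted p-values come from limma.

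The control hairpin line shows what doxycycline does without the targeted knockdown. In shGFP, genes read out from the ERK kinase pathway did not pass the threshold with doxycycline (n = 3 and 3). DUSP6, a phosphatase that ERK induces and that switches ERK off, was at 5541 ± 296 (SD) with doxycycline and 6327 ± 354 without it, a log2 difference of −0.19 ± 0.13. CCND1, which encodes cyclin D1 and drives entry into the cell cycle, differed by −0.21 ± 0.27, and MITF, the master regulator of pigment cells, by 0.08 ± 0.28. SPRY4 differed by −0.08 ± 0.41, ETV5 by −0.12 ± 0.20, CDKN1B by 0.05 ± 0.10 and CYP1A1 by 0.70 ± 0.28, and adjusted p for these 7 genes was 0.858 to 0.998.

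With limma, 1 gene passed the threshold in shGFP, and 804 of 15055 had an unadjusted p under 0.05, near the share of 0.05 that unchanged genes would give. The gene was SLITRK5, a neuronal membrane protein, which fell by 0.82 ± 0.13 (adjusted p = 0.043). In each of the 17 lists 0 genes passed over all genes. Camera nevertheless placed the integrated stress response list, genes induced by amino acid shortage and protein folding stress, lower (median −1.01, adjusted p = 1.21e-18, 13 of 17 lower when adjusted over the list alone, adjusted p = 0.224 with an estimated correlation). It placed the mitosis list higher (median 0.41, adjusted p = 1.16e-09, 0 of 18 adjusted over the list alone, adjusted p = 0.716 with an estimated correlation). The other lists had adjusted p of 0.101 to 0.968. The stress list differed between replicate numbers: its mean over the list was 0.09 lower with Dox in number 1, against 1.38 and 1.49 lower in numbers 2 and 3. Without the Control and Dox arrays numbered 1 of shGFP and shBRaf, an alternative chosen after the data were seen, 804 genes passed in shGFP, 452 higher and 352 lower, among them TRIB3 at −2.20 ± 0.15, DDIT3 at −2.12 ± 0.33 and CHAC1 at −2.95 ± 0.40. The stress list then had 0 genes higher and 15 lower and the mitosis list 15 higher and 0 lower, while CCND1 stood at −0.44 ± 0.12 (adjusted p = 0.0313) and camera placed the ERK list lower (median −0.18, 2 of 24 genes lower, adjusted p = 0.0131, adjusted p = 0.294 with an estimated correlation). With an estimated correlation the stress list had adjusted p = 9.16e-05 and the mitosis list 0.00425 in that fit. The arrays left out were those in which the stress list fell least. The stress list values of that fit therefore follow in part from that choice and are no independent test. Leaving out only shGFP Control 1 gave 86 genes, only shGFP Dox 1 gave 4, and only Control 3, Dox 2 or Dox 3 gave 0.

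The vehicle check in sh2BRaf compared DMSO with Control (n = 2 and 2). DUSP6 was at 4762 ± 39.4 (SD) with DMSO and 4517 ± 309 without. Differences were 0.08 for DUSP6, 0.01 for SPRY4, −0.08 for ETV5, −0.01 for CCND1, 0.06 for MITF, 0.09 for CDKN1B and 0.36 for CYP1A1, all with adjusted p = 1. With limma 0 genes passed, 235 of 15055 had an unadjusted p under 0.05, and the lowest adjusted p was 0.321. That is below the share of 0.05 that unchanged genes would give. Camera placed the stress response list higher (median 0.25, adjusted p = 0.00594, 0 of 17 over all genes and 0 adjusted over the list alone, adjusted p = 0.945 with an estimated correlation). Leaving out DMSO 2 of sh2BRaf gave 4 genes, and leaving out any other of these 4 arrays gave 1.

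**Figure D1:**
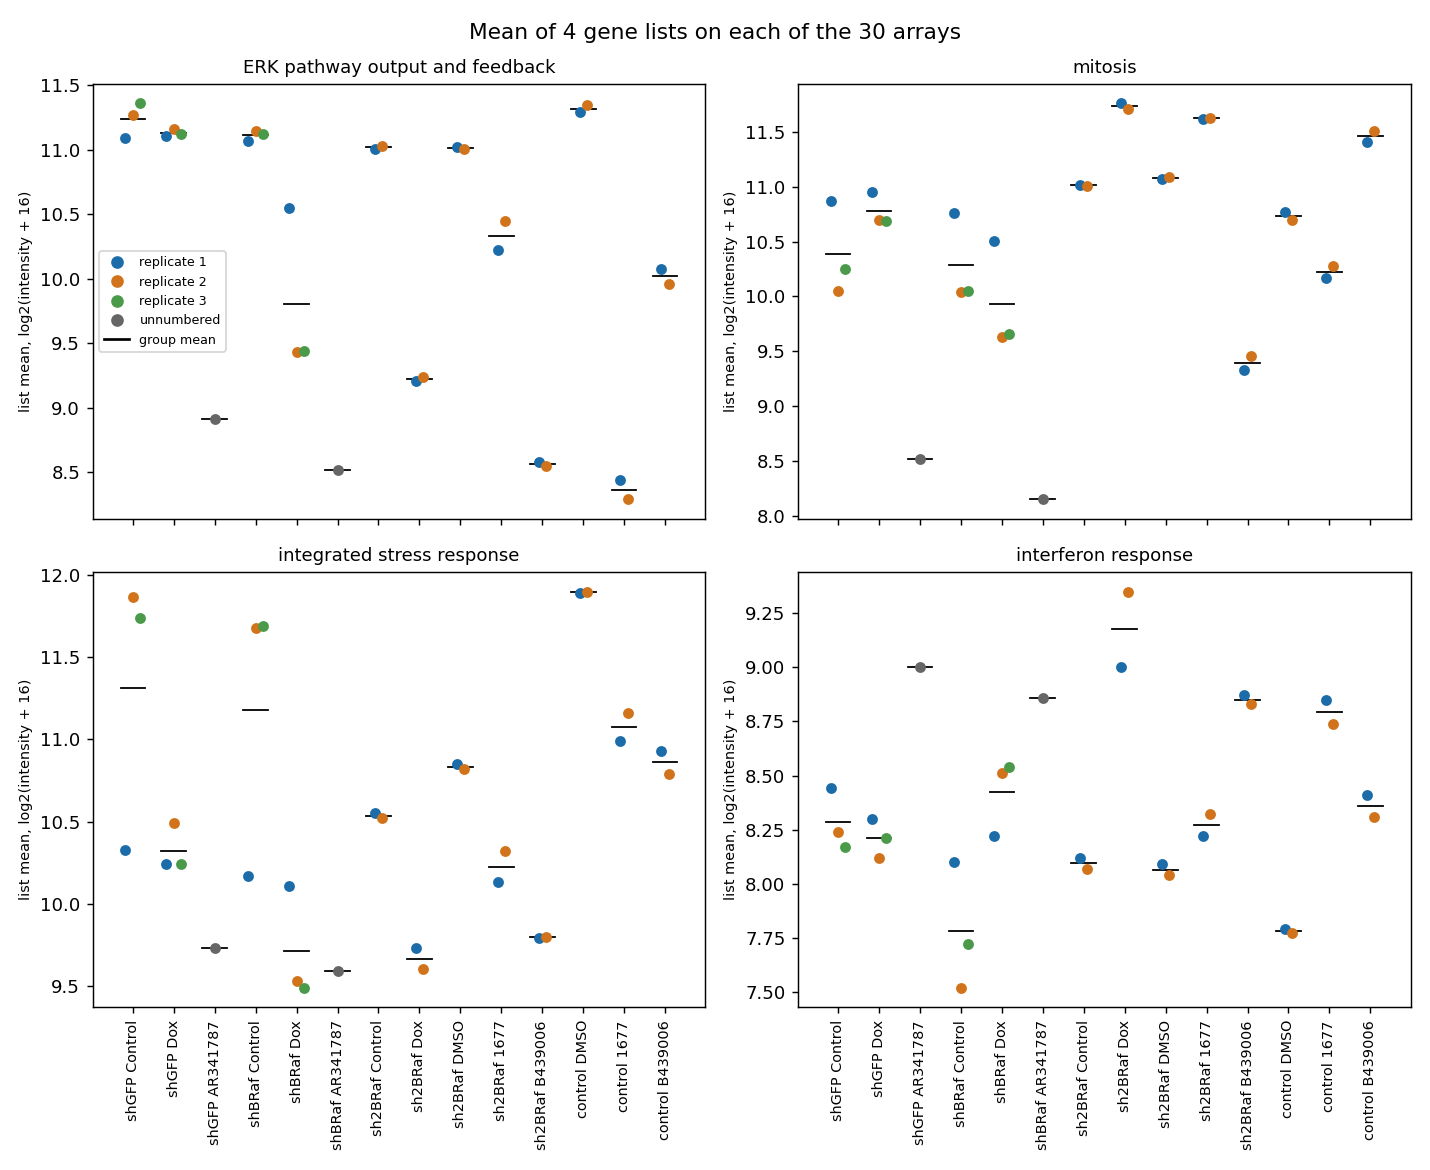
Mean log2 intensity of 4 gene lists (ERK pathway output, mitosis, integrated stress response, interferon response) on each of the 30 arrays, coloured by replicate number, with bars at group means. In the stress response list the shGFP and shBRaf Control arrays numbered 1 lie at 10.33 and 10.17, below those numbered 2 and 3 at 11.68 to 11.87.

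Doxycycline in shBRaf addresses the induced knockdown that the series describes (n = 3 and 3). The ERK readout fell: DUSP6 went from 6672 ± 160 (SD) to 2607 ± 846, a change of −1.40 ± 0.13 (adjusted p = 1.11e-06). SPRY2 and SPRY4, feedback inhibitors of the same pathway, fell by 1.28 ± 0.10 (adjusted p = 8.32e-08) and 2.21 ± 0.41 (adjusted p = 0.000622). CXCL8, which encodes the chemokine interleukin 8, had the lowest value, −4.67 ± 0.50 (adjusted p = 3.56e-06), and SOX8, a neural crest transcription factor, followed at −3.97 ± 0.32 (adjusted p = 2.01e-07). With doxycycline SOX8 was at 12.6 ± 1.30 (SD), under the 16 added before log2. CCND1 fell by 1.31 ± 0.27 (adjusted p = 0.00142) and MITF rose by 1.29 ± 0.28 (adjusted p = 0.00228). ETV5 (−0.49 ± 0.20, adjusted p = 0.0966), CDKN1B (0.06 ± 0.10, 0.741) and CYP1A1 (0.44 ± 0.28, 0.301) did not pass. The SE and adjusted p here, and for the difference from shGFP below, rest on a spread shared by all 14 groups. The shBRaf Dox arrays varied widely, as in SPRY4 (1939 ± 2063, SD) and ETV5 (1878 ± 1037). These SE and p-values may therefore be too small for this line, and far fewer genes passed in a fit of only the groups compared.

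With doxycycline in shBRaf, 1705 genes were higher and 1331 lower, of which 247 and 386 changed at least 2-fold. The genes with the highest values were SPP1 (3.50 ± 0.58), a secreted matrix protein, PCDH7 (3.37), HPGD (3.15), MGP (3.13), MATN2 (3.09) and GPNMB (2.91 ± 0.42), a melanosome glycoprotein. After CXCL8 and SOX8 the lowest were IGFBP3 and TMEM158 (both −3.56), TRAF1 (−3.35) and ADAMTS1 (−3.32). Of the ERK output list, 0 genes were higher and 18 lower of 24 (20 lower adjusted over the list alone, median −1.15, camera adjusted p = 1.17e-15, adjusted p = 0.0508 with an estimated correlation). The stress response list had 10 of 17 lower (13 adjusted over the list alone, median −1.45, adjusted p = 6.21e-10, adjusted p = 0.272 with an estimated correlation), with SLC7A11 at −3.12, MTHFD2 at −1.50 and CEBPB at −1.33. As in shGFP, this fall differed between replicate numbers: the list mean was 0.06 lower with Dox in number 1, against 2.15 and 2.20 lower in numbers 2 and 3, so it cannot be read as a response to the hairpin alone. DNA replication had 6 of 20 lower (7 adjusted over the list alone, median −0.50, adjusted p = 9.4e-05, adjusted p = 0.551 with an estimated correlation), among them RFC3 (−0.77) and MCM7 (−0.72). In the mitosis list 0 of 18 passed either way (0 adjusted over the list alone), yet camera placed it lower (median −0.34, adjusted p = 0.00488, adjusted p = 0.798 with an estimated correlation).

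Invasion and matrix had 7 of 14 lower and 2 higher in shBRaf (8 and 2 adjusted over the list alone, median −0.88, adjusted p = 0.003, adjusted p = 0.272 with an estimated correlation), led by NT5E (−2.80) and PLAUR (−1.68). Glycolysis had 5 of 16 lower and 1 higher (5 and 1 adjusted over the list alone, median −0.10, adjusted p = 0.00794, adjusted p = 0.307 with an estimated correlation). The interferon response had 6 of 14 higher and 0 lower (7 adjusted over the list alone, median 0.46, adjusted p = 0.000778, adjusted p = 0.272 with an estimated correlation), with IFIT1 at 2.43 and IFIT2 at 1.55. The remaining lists were not placed either way, with adjusted p of 0.195 for ribosome biogenesis to 0.847 for cell cycle inhibitors, and melanocyte genes had a median of −0.01 beside a mean of 0.31. Single members of these lists passed: BCL2L11, which promotes cell death, rose by 1.05, PMAIP1 fell by 2.27, the receptor AXL fell by 1.13, and MAP2K1, the gene of MEK1, fell by 0.42. WDR12 (−0.26) had only 1 of 3 bright probe sets in that direction and PFKP (−0.78) 1 of 2.

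The difference of the doxycycline effect between shBRaf and shGFP sets these changes against the control hairpin. It passed for DUSP6 (−1.21 ± 0.19, adjusted p = 0.00107), SPRY4 (−2.13 ± 0.58, adjusted p = 0.0291), CXCL8 (−4.40 ± 0.71, adjusted p = 0.00134) and SOX8 (−3.55 ± 0.46, adjusted p = 0.000211), and for TMEM158 (−3.58), MATN2 (3.67), SPP1 (3.55) and MGP (3.36). CCND1 (−1.09 ± 0.38, adjusted p = 0.0841), MITF (1.21 ± 0.40, adjusted p = 0.0673), ETV5 (−0.36, 0.508), CDKN1B (0.02) and CYP1A1 (−0.25) did not pass. The SPRY4 call was kept in 5 of 12 fits without 1 array. Of 1106 genes, 592 were more positive in shBRaf and 514 more negative. The ERK list had 8 of 24 lower (16 adjusted over the list alone, median −1.09, adjusted p = 2.07e-13, adjusted p = 0.0891 with an estimated correlation), and the interferon list 5 of 14 higher (7 adjusted over the list alone, median 0.61, adjusted p = 0.000111, adjusted p = 0.17 with an estimated correlation). The stress list had 0 of 17 (0 adjusted over the list alone, median −0.33, adjusted p = 0.0419, adjusted p = 0.736 with an estimated correlation). The mitosis list had 1 of 18 lower (9 adjusted over the list alone, median −0.67, adjusted p = 2.54e-07, adjusted p = 0.409 with an estimated correlation) and DNA replication 3 of 20 (3 adjusted over the list alone, median −0.56, adjusted p = 4.59e-06, adjusted p = 0.411 with an estimated correlation). Invasion and matrix had 5 of 14 lower (8 lower and 1 higher adjusted over the list alone, median −1.11, adjusted p = 0.000407, adjusted p = 0.17 with an estimated correlation) and glycolysis 4 of 16 lower (4 lower and 1 higher adjusted over the list alone, median −0.15, adjusted p = 0.00229, adjusted p = 0.241 with an estimated correlation).

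The array shBRaf Dox 1 stood apart from the other Dox arrays, with an ERK list mean of 10.55 against 9.43 and 9.44, Control arrays at 11.07 to 11.15, the lowest mean correlation with its replicates (0.947) and the highest ACTB (2.227) and GAPDH (1.229) ratios of the 30 arrays. Fitted on only the groups compared, 8 genes passed for doxycycline in shBRaf and 26 for the difference from shGFP. Without the Control and Dox arrays numbered 1 of shGFP and shBRaf the counts were 5093 and 3503, with SPRY4 at −3.17 and ETV5 at −0.90 (adjusted p = 5.45e-07) in shBRaf, and differences from shGFP of −0.85 for ETV5, −1.44 for CCND1 and 1.64 for MITF, all past the threshold. That fit was chosen after the data were seen. It leaves out the shBRaf Dox array with the highest ERK list mean and the Control arrays with the lowest stress list means. Its values for both lists and their genes therefore follow in part from that choice and are no independent test. In that fit the ERK list had 20 of 24 lower in shBRaf (camera adjusted p = 1.29e-14, 0.00139 with an estimated correlation). For the difference from shGFP it had 18 of 24 lower (adjusted p = 2.47e-13, 0.00199 estimated), and invasion and matrix 8 of 14 lower and 3 higher (adjusted p = 0.000265, 0.0204 estimated). Mitosis had 11 of 18 lower in shBRaf (adjusted p = 0.000139, 0.213 with an estimated correlation), DNA replication 15 of 20 (adjusted p = 1.43e-06, 0.204 estimated) and the stress list 16 of 17 (adjusted p = 5.08e-17, 0.00314 estimated). For the difference from shGFP mitosis had 17 of 18 lower (adjusted p = 2.47e-13, 0.0204 with an estimated correlation), DNA replication 15 of 20 (adjusted p = 2.67e-09, 0.0933 estimated) and the stress list 8 of 17 (median −0.77, adjusted p = 0.000142, 0.114 estimated), so that these list counts depend on the arrays numbered 1. Leaving out shBRaf Dox 2 alone gave 2021 genes in shBRaf and 541 for the difference, which stood at 2868 without shBRaf Dox 1, 727 without shGFP Control 2, 731 without shGFP Control 3 and 730 without shGFP Dox 3.

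The line labelled sh2BRaf asks the same question with another hairpin (n = 2 and 2). DUSP6 fell from 4517 ± 309 (SD) to 2459 ± 5.27, by 0.87 ± 0.16 (adjusted p = 0.000356). SPRY4 fell by 4.22 ± 0.50 (adjusted p = 2.71e-06) and ETV5, a transcription factor that ERK activity maintains, by 1.87 ± 0.25 (adjusted p = 9.77e-06). CCND1 fell by 1.53 ± 0.33 (adjusted p = 0.00132), and MITF rose by 1.40 ± 0.34 (adjusted p = 0.00414). HPGD, a prostaglandin-degrading enzyme, rose by 6.25 ± 0.81 (adjusted p = 7.92e-06), and MGP, an inhibitor of matrix calcification, by 6.05 ± 0.57 (adjusted p = 1.67e-07). CDKN1B (−0.18 ± 0.13, adjusted p = 0.356) and CYP1A1 (0.71 ± 0.34, adjusted p = 0.146) did not pass.

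Here 1708 genes were higher and 2090 lower, 509 and 761 of them at least 2-fold. Next to HPGD and MGP the highest were COL14A1 (5.59), MATN2 (5.37), OLFML2A (5.28) and ANGPTL7 (5.27). The lowest were CXCL8 (−5.39 ± 0.62), CEMIP (−4.82), EGR1 (−4.65) and, all at −4.41, SOX8, MIR100HG and NOX4. Of the ERK list, 19 of 24 genes were lower (20 adjusted over the list alone, median −1.49, adjusted p = 9.42e-14, adjusted p = 0.0667 with an estimated correlation). The interferon list had 10 of 14 higher (10 adjusted over the list alone, median 0.90, adjusted p = 7.6e-07, adjusted p = 0.0667 with an estimated correlation), led by IFIT3 (2.18) and IFIT2 (2.07). The stress list had 7 of 17 lower and 0 higher (9 and 1 adjusted over the list alone, median −1.01, adjusted p = 0.024, adjusted p = 0.776 with an estimated correlation). The mitosis list had 8 of 18 higher (11 adjusted over the list alone, median 0.73, adjusted p = 4.32e-05, adjusted p = 0.776 with an estimated correlation), among them CENPE (1.47), CDC20 (1.16) and CENPF (1.02). The other lists had adjusted p of 0.0622 for p53 targets, with 6 of 11 higher and 2 lower, to 0.913. Members that passed in them included GPNMB (3.51), CAPN3 (2.14), TP53INP1 (1.73), HRAS (0.66), ITGA2 (3.06), ITGA3 (−2.65), IGF1R (−1.51), STARD4 (−2.17) and PFKFB3 (−2.33). KRT14, a marker of another cell type, rose by 1.51 ± 0.30 (adjusted p = 0.000649), which differed from shGFP by 1.57 ± 0.38 (adjusted p = 0.00655). Fitted on only the groups compared, 6668 genes passed, against 2410 without sh2BRaf Control 2 and 2490 without sh2BRaf Dox 1.

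Against shGFP, the doxycycline effect in sh2BRaf differed for 2579 genes, 1116 more positive and 1463 more negative. The difference passed for DUSP6 (−0.68 ± 0.21, adjusted p = 0.0277), SPRY4 (−4.14 ± 0.65, adjusted p = 0.000141), ETV5 (−1.75 ± 0.32, adjusted p = 0.000606), CCND1 (−1.32 ± 0.42, adjusted p = 0.0352) and MITF (1.32 ± 0.44, adjusted p = 0.0443). In 10 fits without 1 array, MITF kept its call in 0, CCND1 in 3 and DUSP6 in 4. It was largest for TAC1 (6.34), MGP (6.27), HPGD (6.12), CXCL8 (−5.12), SIRPB1 and MIR100HG (both −4.62), while CDKN1B (−0.22) and CYP1A1 (0.01) did not pass. In sh2BRaf TAC1 rose from 203 ± 0.445 (SD) to 4453 ± 60.7 and was not among the highest genes. Part of its difference thus lay in shGFP. The ERK list had 16 of 24 lower (17 adjusted over the list alone, median −1.54, adjusted p = 8.79e-12, adjusted p = 0.0687 with an estimated correlation). Interferon genes had 7 of 14 higher (9 adjusted over the list alone, median 1.26, adjusted p = 3.31e-07, adjusted p = 0.0687 with an estimated correlation), and the mitosis list was not placed (1 of 18 higher, 0 adjusted over the list alone, adjusted p = 0.135). The count was 1660 without sh2BRaf Control 2, 1639 without sh2BRaf Dox 1 and 4214 without the arrays numbered 1 of shGFP and shBRaf.

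Between the hairpin lines shBRaf and sh2BRaf, 1281 genes differed in the doxycycline effect, 826 more positive in shBRaf and 455 more negative. KRT14 differed by −1.25 (adjusted p = 0.0463), with intensities of 9.71 in Control and 14.4 with doxycycline in shBRaf, close to background. The ETV5 call below was kept in 8 of 10 fits without 1 array. ETV5 differed by 1.38 ± 0.32 (adjusted p = 0.0091), whereas DUSP6 (−0.52, adjusted p = 0.133), SPRY4 (2.01, 0.0599), CCND1 (0.22), MITF (−0.11), CDKN1B (0.24) and CYP1A1 (−0.27) did not pass. The widest differences were in PDE9A (3.54 ± 0.39), ITGA9 (3.01), ACSF2 (2.77), TAC1 (−7.25 ± 1.16), NIBAN1 (−4.78 ± 0.76) and DMD (−3.72). The shBRaf Control arrays varied widely for TAC1 (1604 ± 1247, SD) and NIBAN1 (2648 ± 1729), so part of these differences may come from them. PDE9A had 1 of 2 bright probe sets in that direction. It was at 8.29 ± 1.15 (SD) with doxycycline in sh2BRaf, under the 16 added before log2. DMD had 2 of 3 bright probe sets in that direction and was at 14.5 ± 11.5 (SD) in sh2BRaf Control, also under 16. The mitosis list was lower in shBRaf than in sh2BRaf, 8 of 18 (16 adjusted over the list alone, median −1.01, adjusted p = 2.11e-11, adjusted p = 0.44 with an estimated correlation), with CENPE at −1.87 and BIRC5 at −1.43. DNA replication (0 of 20, 0 adjusted over the list alone, median −0.40, adjusted p = 0.0012, adjusted p = 0.683 with an estimated correlation) and the interferon list (2 of 14 lower, 3 adjusted over the list alone, median −0.45, adjusted p = 0.00509, adjusted p = 0.44 with an estimated correlation) were placed lower too. Fitted on only the groups compared the count was 278, and it was 2847 without the arrays numbered 1 of shGFP and shBRaf, 543 without sh2BRaf Control 2, 657 without sh2BRaf Control 1, 630 without sh2BRaf Dox 1 and 657 without sh2BRaf Dox 2.

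AR341787, which the series describes as a small molecule, lowered the ERK readout in both lines that received it (n = 1 array in each line against 3 Control arrays in each). Its vehicle is not given in the sources used here, so the contrast has no known vehicle control. DUSP6 was at 922 in shGFP and 865 in shBRaf, against 6327 ± 354 (SD) and 6672 ± 160 in Control, a mean change of −2.84 ± 0.16 (adjusted p = 2.66e-07). SPRY4 fell by 5.36 ± 0.51 (adjusted p = 9.3e-06), ETV5 by 3.49 ± 0.26 (adjusted p = 2.05e-06) and CCND1 by 3.15 ± 0.33 (adjusted p = 1.91e-05). CCN3, a secreted matrix protein linked to growth arrest, rose by 5.89 ± 0.53 (adjusted p = 6.51e-06), and CEMIP, which breaks down hyaluronan, fell by 6.18 ± 0.76 (adjusted p = 5.82e-05). MITF (0.96 ± 0.35, adjusted p = 0.0518), CDKN1B (−0.01, 0.955) and CYP1A1 (0.41, 0.392) did not pass.

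With AR341787, 2310 genes were higher and 2412 lower, 671 and 937 at least 2-fold. Changes in the 2 lines, each on a single array, correlated at r = 0.80 across genes, which are not independent replicates. TCN1 (5.65), ANGPTL7 (4.45), MYLK (4.31), GASK1B (4.21) and JUN (4.11) followed CCN3, and EGR1 (−5.66), CXCL8 (−5.26), TMEM158 (−5.18) and FST (−4.73) followed CEMIP. Of the 24 ERK list genes, 22 were lower (23 adjusted over the list alone, median −2.46, adjusted p = 4.74e-17, adjusted p = 0.0888 with an estimated correlation). Proliferation genes fell as a group: 19 of 20 for DNA replication (19 adjusted over the list alone, median −1.64, adjusted p = 9.53e-13, adjusted p = 0.195 with an estimated correlation) and 18 of 18 for mitosis (18 adjusted over the list alone, median −2.06, adjusted p = 2.44e-13, adjusted p = 0.195 with an estimated correlation), with RFC3 at −2.38 and UBE2C at −2.59. Ribosome biogenesis had 10 of 15 lower (10 adjusted over the list alone, median −0.71, adjusted p = 6.55e-07, adjusted p = 0.195 with an estimated correlation) and the stress list 12 of 17 lower and 0 higher (13 and 1 adjusted over the list alone, median −1.46, adjusted p = 4.57e-05, adjusted p = 0.44 with an estimated correlation). The raised Control arrays numbered 2 and 3 carry much of that stress list value, since its mean was 9.73 and 9.59 with AR341787 in shGFP and shBRaf, 10.33 and 10.17 on the Control arrays numbered 1, and 11.68 to 11.87 on the others. The interferon list had 10 of 14 higher (11 adjusted over the list alone, median 0.82, adjusted p = 0.000181, adjusted p = 0.195 with an estimated correlation) and p53 targets 7 of 11 higher and 1 lower (8 and 2 adjusted over the list alone, median 0.45, adjusted p = 0.0157, adjusted p = 0.195 with an estimated correlation). BMF (2.73), GPNMB (3.39), CYP1B1 (2.96) and BCL2A1 (2.24) rose, and PMAIP1 (−3.95) and NT5E (−4.31) fell. Of the markers of other cell types the keratin gene KRT14 rose by 2.88 ± 0.30 (adjusted p = 1.89e-05) and HBB fell by 0.50 (adjusted p = 0.0445). KRT14 was at 35.4 ± 6.51 (SD) and 9.71 ± 6.51 in Control of shGFP and shBRaf, and at 331 and 185 with AR341787. For HBB 3 of 4 bright probe sets moved that way, and the mean of all its probe sets turned to 0.14. The count was 1760 without the shBRaf array with AR341787 and 2506 without the shGFP one.

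The pair of compounds was compared at the same labelled dose in A375control (n = 2 each, 2 with DMSO). On the arrays labelled A375control_1677, DUSP6 fell from 8590 ± 584 (SD) to 290 ± 2.38, by 4.81 ± 0.16 (adjusted p = 1.32e-14), and SPRY4 by 4.81 ± 0.50 (adjusted p = 3.91e-07). ETV5 fell by 3.74 ± 0.25 (adjusted p = 1.26e-09), CCND1 went from 5436 ± 54.4 (SD) to 326 ± 34.4 (adjusted p = 1.79e-08), and EGR1, an immediate early transcription factor, had the lowest value, −6.39 ± 0.82 (adjusted p = 4.08e-06). MITF rose by 1.33 ± 0.34 (adjusted p = 0.00486), and CDKN1B, which encodes the cell cycle inhibitor p27, rose by 0.61 ± 0.13 (adjusted p = 0.000803). CYP1A1, a sensor of the aryl hydrocarbon receptor, was at 0.02 ± 0.34 (adjusted p = 0.978).

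For A375control_1677 against DMSO, 2522 genes were higher and 2184 lower, 805 and 779 at least 2-fold. TCN1 (5.17), CCN3 (5.01), LINC01549 (4.91) and MYLK (4.54) were highest, and CEMIP (−5.75), ETV4 (−5.07) and CXCL8 (−4.84) were low beside EGR1. ERK list genes were lower in 23 of 24 cases (23 adjusted over the list alone, median −2.88, adjusted p = 1.19e-24, adjusted p = 0.00747 with an estimated correlation). DNA replication had 15 of 20 lower (16 adjusted over the list alone, median −1.31, adjusted p = 5.12e-09, adjusted p = 0.305 with an estimated correlation), mitosis 5 of 18 (5 adjusted over the list alone, median −0.55, adjusted p = 0.0105, adjusted p = 0.696 with an estimated correlation) and ribosome biogenesis 11 of 15 (12 adjusted over the list alone, median −0.95, adjusted p = 5.43e-08, adjusted p = 0.109 with an estimated correlation). In the stress list 6 of 17 were lower (6 adjusted over the list alone, median −0.97, adjusted p = 0.024, adjusted p = 0.696 with an estimated correlation), and in the interferon list 8 of 14 were higher (9 adjusted over the list alone, median 0.84, adjusted p = 0.000506, adjusted p = 0.187 with an estimated correlation). Cell cycle inhibitors had 6 of 13 higher and 2 lower (7 and 2 adjusted over the list alone, median 0.56, adjusted p = 0.0428, adjusted p = 0.131 with an estimated correlation), with TOB1 at 1.37 and CCNG2 at 0.81. The other lists had adjusted p of 0.218 to 0.908, though BMF (3.03), TP53INP1 (2.52), BCL2L11 (1.86) and GPNMB (3.04) rose and OCA2 (−3.05) fell. Fitted on only the groups compared, 7066 genes passed.

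On the arrays labelled A375control_B439006, DUSP6 fell to 2666 ± 31.0, by 1.68 ± 0.16 (adjusted p = 3.78e-08), and CCND1 by 2.76 ± 0.33 (adjusted p = 6.38e-07). SPRY4 fell by 3.18 ± 0.50 (adjusted p = 2.5e-05), ETV5 by 1.05 ± 0.25 (adjusted p = 0.00158), CDKN1B by 0.76 ± 0.13 (adjusted p = 4.58e-05) and CYP1A1 by 0.97 ± 0.34 (adjusted p = 0.0265). MITF was at 0.45 (adjusted p = 0.31). NF1, an inhibitor of RAS, had the highest value, 4.09 ± 0.35 (adjusted p = 7.12e-09), ahead of HRCT1 (3.69), GADD45B (3.66) and KRT14 (3.46). PMEPA1 (−5.94), KLF3 (−5.72 ± 0.29), a transcriptional repressor, GSK3B (−4.58) and EGR1 (−4.51) were lowest. On these arrays KLF3 was at 13.35 ± 11.4 (SD), under the 16 added before log2. Of the passing genes 2920 were higher and 3498 lower, 745 and 1803 at least 2-fold. The ERK list had 16 of 24 lower and 2 higher (17 and 2 adjusted over the list alone, median −1.33, adjusted p = 0.000103, adjusted p = 0.45 with an estimated correlation). Mitosis had 11 of 18 higher (11 adjusted over the list alone, median 0.73, adjusted p = 0.00624, adjusted p = 0.688 with an estimated correlation), led by CDC20 (1.79), and cholesterol biosynthesis 5 of 11 higher (5 adjusted over the list alone, median 0.57, adjusted p = 0.0462, adjusted p = 0.45 with an estimated correlation), led by HMGCS1 (1.52). The other lists were not placed. Receptor tyrosine kinases had 7 of 11 lower (adjusted p = 0.0778), with MET at −2.19 and IGF1R at −1.81. MDM2 (−1.45) was lower on 5 of 8 bright probe sets, and RAB27A (0.83) was higher on 2 of 5. CYP1A1 kept its call in 1 of 4 fits without 1 array (−1.36 to −0.58).

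Set directly against A375control_B439006, A375control_1677 had higher values for 4084 genes and lower ones for 3354. It was lower for DUSP6 (−3.13, adjusted p = 3.57e-12), ETV5 (−2.69), SPRY4 (−1.63, adjusted p = 0.0101) and CCND1 (−1.24, adjusted p = 0.00318), and higher for CDKN1B (1.37), CYP1A1 (0.99, adjusted p = 0.0207) and MITF (0.87, adjusted p = 0.0394). In 4 fits without 1 array the SPRY4 call was kept in 2, CYP1A1 in 1 and MITF in 0. KLF3 (5.59), PMEPA1 (5.53) and CYP1B1 (5.26) differed most upward, and CEMIP (−5.51), CCN1 (−5.42) and MYC (−4.82) most downward. The ERK list was lower in 18 of 24 and higher in 3 (19 and 3 adjusted over the list alone, median −1.78, adjusted p = 1e-05), DNA replication in 17 of 20 and 1 (18 and 2 adjusted over the list alone, median −1.65, adjusted p = 7.52e-07), mitosis in 15 of 18 and 0 (15 and 0 adjusted over the list alone, median −1.32, adjusted p = 1.11e-05) and ribosome biogenesis in 12 of 15 and 1 (12 and 1 adjusted over the list alone, median −0.66, adjusted p = 0.000582). Each of these lists had adjusted p = 0.39 with an estimated correlation.

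The same pair of labels was compared with DMSO in sh2BRaf (n = 2 each, 2 with DMSO). On arrays labelled A375sh2BRaf_1677, DUSP6 was at 3267 ± 453 (SD) against 4762 ± 39.4 with DMSO, a fall of 0.55 ± 0.16 (adjusted p = 0.0111), and CCND1 fell by 1.37 ± 0.33 (adjusted p = 0.00219), although 1 of its 2 bright probe sets moved that way. SPRY4 fell by 2.87 ± 0.50 (adjusted p = 0.000111), ETV5 by 0.68 ± 0.25 (adjusted p = 0.0377), CDKN1B by 0.49 ± 0.13 (adjusted p = 0.00449) and CYP1A1 by 2.09 ± 0.34 (adjusted p = 5.25e-05), and MITF was at −0.64 (adjusted p = 0.161). NF1 rose by 4.56 ± 0.35 (adjusted p = 2.16e-09), with the histone gene H4C11 (4.51) and FOS (4.42), an immediate early gene, behind it. KLF3 (−4.97), PMEPA1 (−4.90) and GSK3B (−4.64) were lowest. Of the passing genes 2200 were higher and 3124 lower, 369 and 1527 at least 2-fold. Of the 17 lists camera placed 1, mitosis, with 5 of 18 higher (5 adjusted over the list alone, median 0.55, adjusted p = 0.0357, adjusted p = 0.852 with an estimated correlation). The ERK list had 10 of 24 lower and 2 higher (12 and 4 adjusted over the list alone, median −0.64, adjusted p = 0.0858). Aryl hydrocarbon receptor targets had 5 of 7 lower (5 adjusted over the list alone, adjusted p = 0.0858), with AHRR at −1.91. KRT14 rose by 1.75 (adjusted p = 7.7e-05), from an intensity of 20.6 ± 4.57 (SD) with DMSO to 107 ± 12.1. Without 1 of the 4 arrays at a time, DUSP6 kept its call in 2 of 4 fits, with values of −0.69 to −0.41, and ETV5 in 0 of 4, with −0.81 to −0.54.

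On arrays labelled A375sh2BRaf_B439006, DUSP6 fell to 299 ± 14.9 (SD), by 3.93 ± 0.16 (adjusted p = 1.59e-12), and SPRY4 fell by 5.29 ± 0.50 (adjusted p = 2.26e-07). ETV5 fell by 3.91 ± 0.25 (adjusted p = 1.08e-09) and CCND1 by 2.66 ± 0.33 (adjusted p = 4.87e-06), while MITF rose by 1.94 ± 0.34 (adjusted p = 0.00023) and CDKN1B by 0.44 ± 0.13 (adjusted p = 0.0138). CYP1A1 was at 0.20 (adjusted p = 0.758). CDKN1B kept its call in 1 of 4 fits without 1 array. TCN1 (5.47), LINC01549 (5.08) and RASGRP3 (4.64) were highest, and CEMIP (−6.66 ± 0.73), EGR1 (−5.16) and ETV4 (−5.02) lowest. Of the passing genes 1955 were higher and 1909 lower, 564 and 741 at least 2-fold. The ERK list had 22 of 24 lower (24 adjusted over the list alone, median −2.26, adjusted p = 8.78e-24, adjusted p = 0.00882 with an estimated correlation). DNA replication had 19 of 20 lower (19 adjusted over the list alone, median −1.89, adjusted p = 1.49e-17, adjusted p = 0.118 with an estimated correlation), mitosis 18 of 18 (18 adjusted over the list alone, median −1.72, adjusted p = 1.06e-15, adjusted p = 0.143 with an estimated correlation) and ribosome biogenesis 10 of 15 (12 adjusted over the list alone, median −0.71, adjusted p = 2.02e-07, adjusted p = 0.118 with an estimated correlation). The stress list had 8 of 17 lower and 1 higher (9 and 1 adjusted over the list alone, median −0.94, adjusted p = 0.00166, adjusted p = 0.482 with an estimated correlation). Interferon genes (6 of 14 higher, 7 adjusted over the list alone, median 0.67, adjusted p = 0.000669, adjusted p = 0.143 with an estimated correlation), p53 targets (5 of 11 higher, 5 adjusted over the list alone, median 0.47, adjusted p = 0.0122, adjusted p = 0.143 with an estimated correlation) and melanocyte genes (5 of 12 higher, 5 adjusted over the list alone, median 0.43, adjusted p = 0.0263, adjusted p = 0.191 with an estimated correlation) were placed higher, with GPNMB at 3.64 and CAPN3 at 3.57. Fitted on only the groups compared the count was 5872, and it was 2483 without DMSO 1, 2506 without DMSO 2 and 2510 without B439006 1.

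The direct difference of A375sh2BRaf_1677 from A375sh2BRaf_B439006 had the opposite sign to that in A375control for each of the 7 genes always named: DUSP6 at 3.38, SPRY4 at 2.42, ETV5 at 3.24, CCND1 at 1.28, MITF at −2.58, CDKN1B at −0.92 and CYP1A1 at −2.29. Of the genes past the threshold, 3158 were higher on the A375sh2BRaf_1677 arrays and 3893 lower, with CEMIP (6.51), FOS (5.41) and ETV4 (5.26) at one end and KLF3 (−6.17), ITGA2 (−5.13) and CYP1B1 (−4.95) at the other. The ERK list was higher in 19 of 24 and lower in 3 (20 and 3 adjusted over the list alone, median 1.79, adjusted p = 5.51e-07), DNA replication in 16 of 20 and 1 (16 and 1 adjusted over the list alone, median 2.04, adjusted p = 7.23e-09) and mitosis in 18 of 18 (18 adjusted over the list alone, median 2.18, adjusted p = 4.26e-11), each with adjusted p = 0.298 with an estimated correlation.

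Tested as a difference between lines, the change of A375sh2BRaf_1677 from DMSO differed from that of A375control_1677 for 5552 genes, with 2253 more positive in sh2BRaf and 3299 more negative. That of A375sh2BRaf_B439006 differed from A375control_B439006 for 5753, with 3217 and 2536. In the first of these the difference was 4.26 ± 0.23 in DUSP6 (adjusted p = 4.35e-11), 3.07 in ETV5, 2.62 in CCND1, 1.94 in SPRY4 (adjusted p = 0.037), −1.97 in MITF, −1.09 in CDKN1B and −2.11 in CYP1A1. GDF15 (6.54), CEMIP (5.60) and ETV4 (5.31) were most positive and MEF2C (−5.40), KLF3 (−4.83) and TMEM127 (−4.78) most negative. For the B439006 groups it was −2.25 in DUSP6, −2.86 in ETV5, −2.11 in SPRY4 (adjusted p = 0.0227), 1.49 in MITF (adjusted p = 0.019) and 1.19 in CDKN1B, while CCND1 (0.10, adjusted p = 0.893) and CYP1A1 (1.17, adjusted p = 0.0631) did not pass. In 8 fits without 1 array the SPRY4 call was kept in 0 for the first difference and 2 for the other, and the MITF call in 6 for the other. KLF3 (6.92), CYP1B1 (6.44) and ZNF536 (5.96) were most positive and CEMIP (−6.42), CCN1 (−6.08) and FOS (−4.32) most negative. In the first of these differences the ERK list was higher in 19 of 24 and lower in 1 (19 and 2 adjusted over the list alone, median 2.45, adjusted p = 7.66e-09, adjusted p = 0.322 with an estimated correlation), and in the other it was lower in 11 and higher in 2 (11 and 2 adjusted over the list alone, median −1.11, adjusted p = 0.00232, adjusted p = 0.337 with an estimated correlation). Mitosis was higher in 9 of 18 in the first (12 adjusted over the list alone, median 1.08, adjusted p = 0.000321, adjusted p = 0.597 with an estimated correlation) and lower in 18 of 18 in the other (18 adjusted over the list alone, median −2.41, adjusted p = 3.03e-11, adjusted p = 0.246 with an estimated correlation). Markers of other cell types were lower in 3 of 5 in the other (3 adjusted over the list alone, median −0.90, adjusted p = 0.04, adjusted p = 0.246 with an estimated correlation): KRT14 at −3.35 (adjusted p = 2.42e-06), PECAM1 at −0.90 (adjusted p = 0.0321) and HBB at −0.81 (adjusted p = 0.0184).

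The 4 arrays labelled A375control_B439006 and A375sh2BRaf_1677 also differed from the other 26 in technical measures. Their upper quartiles were 342.2 to 347.2 against 359.2 to 369.7, and their highest intensities 20667 to 22245 against 28873 to 35626. The spiked-in transcript Dap read 771 to 816 on them and 332.2 to 646.5 on the others, while BioB read 295.6 to 408 and 192.8 to 297. Their ACTB and GAPDH ratios lay within the range of the others.

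**Figure D2:**
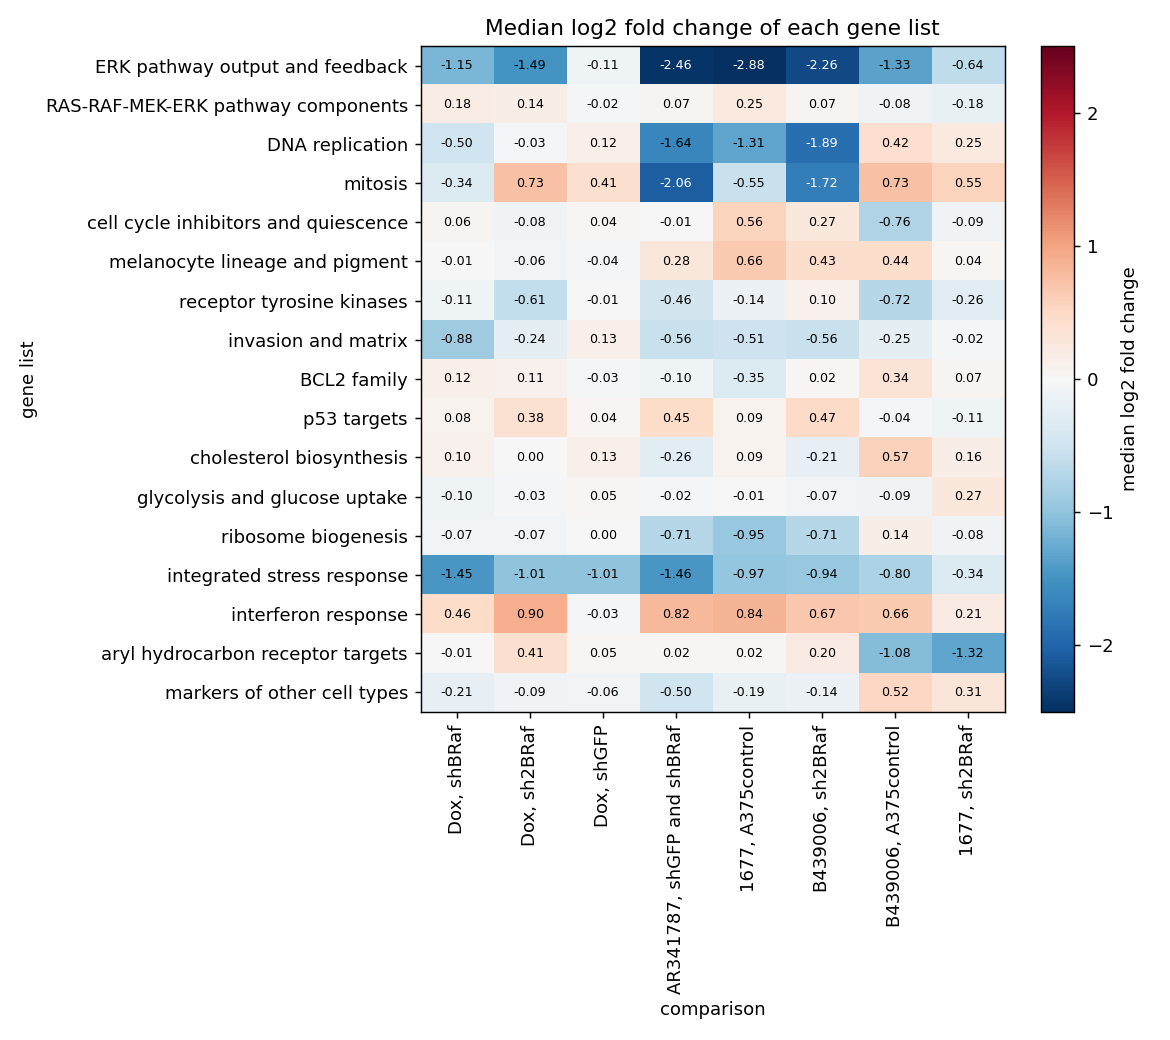
Median log2 fold change of the 17 gene lists (one axis) in 8 comparisons of a treatment with its control (other axis), shown as colour. The ERK list lies at −2.88 for A375control_1677 and −2.26 for A375sh2BRaf_B439006, against −1.33 for A375control_B439006 and −0.64 for A375sh2BRaf_1677.

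The doxycycline effect minus the change of A375sh2BRaf_1677 from DMSO, both in sh2BRaf and with no control array in common, compares doxycycline with the arrays of that label. If the compound labels were exchanged in sh2BRaf, which stays open, it would concern the other compound, and if they were exchanged in A375control it would not. DUSP6 (−0.32, adjusted p = 0.323), SPRY4 (−1.35, 0.167), CCND1 (−0.16, 0.847) and CDKN1B (0.31, 0.217) did not differ past the threshold, whereas ETV5 (−1.19, adjusted p = 0.0122), MITF (2.04, adjusted p = 0.0026) and CYP1A1 (2.80, adjusted p = 0.000136) did, ETV5 in 7 of 8 fits without 1 array. The values were highest for HPGD (5.98), ITGA2 (5.89) and COL14A1 (5.84) and lowest for FOS (−8.36), NF1 (−5.17) and GDF15 (−5.08), with 2609 genes more positive under doxycycline and 2017 more negative. The ERK list was lower in 12 of 24 and higher in 3 (14 and 3 adjusted over the list alone, median −1.27, adjusted p = 0.0116) and the interferon list higher in 6 of 14 (6 adjusted over the list alone, median 0.77, adjusted p = 0.0478), both with adjusted p = 0.835 with an estimated correlation.

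Profiles were compared by the correlation of log2 fold changes across the 15055 genes, which are not independent replicates, between comparisons without a common array. Doxycycline in shBRaf correlated with doxycycline in sh2BRaf at r = 0.57, with 767 genes higher in both (193 if independent), 734 lower in both (185) and 105 in opposite directions. Between single treated arrays this r ran from 0.18 to 0.57. It correlated at 0.60 with A375control_1677 (0.22 to 0.59 between single treated arrays, 1148 higher in both against 286, 853 lower against 193) and at 0.17 with A375control_B439006. Doxycycline in sh2BRaf correlated at 0.12 with A375sh2BRaf_1677 and at 0.50 with A375sh2BRaf_B439006 (838 higher in both against 222, 810 lower against 265). Doxycycline in shGFP correlated at 0.10 with doxycycline in shBRaf and 0.02 with it in sh2BRaf.

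The same compound label did not give the same profile in both lines, with r = −0.01 for A375control_1677 with A375sh2BRaf_1677 (1184 genes in opposite directions) and 0.06 for the B439006 groups (1043). Across labels, A375control_1677 correlated at 0.72 with A375sh2BRaf_B439006 (1430 higher in both against 327 if independent, 1321 lower against 277, 20 opposite). A375control_B439006 correlated at 0.76 with A375sh2BRaf_1677 (1613 against 427, 2517 against 726, 26 opposite). AR341787 correlated at 0.69 with A375control_1677 and 0.75 with A375sh2BRaf_B439006, against 0.12 and 0.08 with the other 2, and at 0.55 with doxycycline in sh2BRaf.

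Some pairs had control arrays in common, for which 20 simulations of unchanged groups gave the value with no effect. Doxycycline in shBRaf and AR341787 correlated at r = 0.61 (simulated 0.25) with a covariance of 0.218 (simulated 0.0188), 965 genes higher in both against 262 if independent and 809 lower against 213. The A375control_1677 and A375control_B439006 changes correlated at 0.22 (simulated 0.50, covariance 0.133, simulated 0.0562, 894 higher against 489, 800 lower against 507), and the same codes in sh2BRaf at 0.08 (simulated 0.50, covariance 0.0409, simulated 0.0565, 397 against 286, 440 against 396). These controls were not split, so part of the excess may come from the shared controls. With AR341787 in shGFP alone, which has no Control array in common with shBRaf, the correlation of doxycycline in shBRaf was 0.53, although same-numbered Control arrays of these lines deviated together (r = 0.43, 0.12 and 0.16), so this value is not free of shared control variation either.

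**Figure D3:**
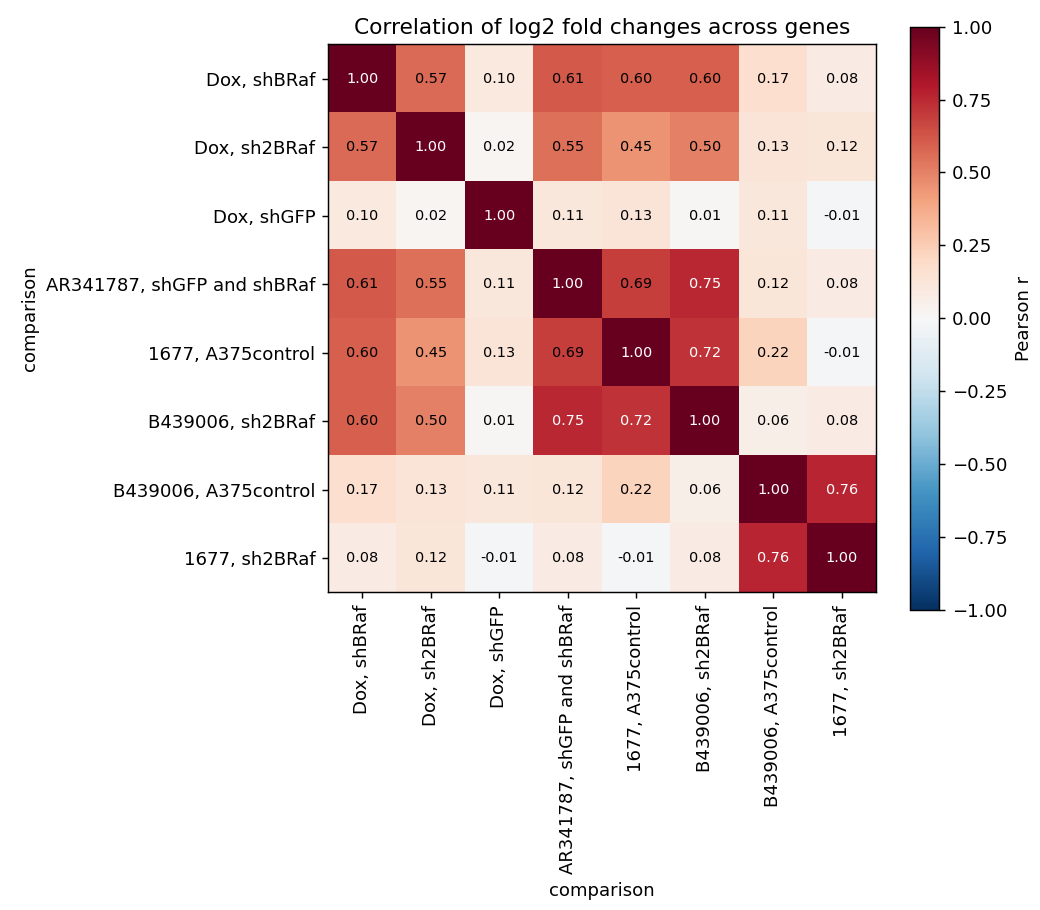
Correlation across genes of log2 fold changes among 8 comparisons, shown as colour with r printed in each cell. The pairs across compound labels between the lines stand at 0.72 and 0.76, and the pairs with the same label at −0.01 and 0.06.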

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

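Tests chosen only after the result was seen were the correlations across compound labels, the list means by replicate number, the tests of the array shBRaf Dox 1, the splits of the arrays and the fit without the Control and Dox arrays numbered 1. The counts and gene values of differences below were picked out because 2 lines differed in the effect of the same treatment, past the threshold of limma's test of that difference. The stress list in shGFP and the array shBRaf Dox 1 are no such differences and are weighed because they bear on them.

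The effect of a compound label differed between the lines for 5552 genes (A375sh2BRaf_1677 minus A375control_1677, each against DMSO) and for 5753 genes (the B439006 groups). The lower correlation across the labels lay 0.67 above the higher one of the same label, which is consistent with exchanged compound labels in 1 line. A difference in overall brightness of the arrays is argued against. After quantile normalization, which gives all arrays 1 distribution, the lower correlation across the labels was still 0.72. The pair A375control_1677 and A375sh2BRaf_B439006 holds none of the arrays with the low highest intensities (20667 to 22245 against 28873 to 35626). The treated arrays of the other pair are those arrays. A technical effect on some probe sets only, which this scaling would leave, was not tested for that pair. A response to each compound that depends on the line or its dose cannot be told apart from exchanged labels, because the doses in sh2BRaf are not in the labels, and the larger count of genes differing between the lines across the labels, 401, decides neither. The arrays are named here as labelled.

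For the A375sh2BRaf_1677 change minus the A375control_1677 change the values were 4.26 for DUSP6, 1.94 for SPRY4, 3.07 for ETV5, 2.62 for CCND1, −1.97 for MITF, −1.09 for CDKN1B, −2.11 for CYP1A1, 6.54 for GDF15, 5.60 for CEMIP, 5.31 for ETV4, −5.40 for MEF2C, −4.83 for KLF3 and −4.78 for TMEM127. The SPRY4 difference kept its call in 0 of 8 fits of limma without 1 array (1.81 to 2.07). For the B439006 groups they were −2.25 for DUSP6, −2.11 for SPRY4, −2.86 for ETV5, 1.49 for MITF, 1.19 for CDKN1B, 6.92 for KLF3, 6.44 for CYP1B1, 5.96 for ZNF536, −6.42 for CEMIP, −6.08 for CCN1 and −4.32 for FOS, with the SPRY4 call kept in 2 and the MITF call in 6 of 8 such fits.

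The lower stress response list with doxycycline in shGFP bears on the difference between shBRaf and shGFP. The 4 Control arrays numbered 2 and 3 of both lines all lay at least 1.19 above the other 8 Control and Dox arrays in that list's mean, so that a culture or batch difference of those arrays may account for it. The Dox minus Control difference of the list mean was −0.09 in number 1 of shGFP and −0.06 in number 1 of shBRaf, with 1 array a side. This speaks against doxycycline acting alike on every numbered pair only if same numbers are pairs, which the labels do not say. These values are also part of the pattern itself and so no separate test of it. Doxycycline acting only where the Control level was high, where the smallest fall of the pairs numbered 2 and 3 was −1.38, cannot be told apart from a culture difference, because no label names a batch. In shGFP 1 gene passed and the highest of the other splits of its 6 arrays gave 16, where 3 of the 10 splits gave at least as many as the real one; 10 splits are too few for a share under 0.05.

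The array shBRaf Dox 1 lay between the Control and the other Dox arrays. Lower RNA integrity cannot be told apart from the others: this array had the highest ACTB and GAPDH ratios (2.227 and 1.229), and its deviation correlated at 0.01 across genes with that of shGFP Dox 2, which has the next highest ACTB ratio (2.034) but a GAPDH ratio of 0.9692, so that no comparable array was at hand. A label exchanged with a Control array is argued against, since the lowest ERK list mean of the Control arrays, 11.07, lay above the highest of the Dox arrays, 10.55. A weaker response on that array may account for it: over the 3798 genes called for doxycycline in sh2BRaf its change had a slope of 0.15 on the change there (r = 0.41), which shares no array with it, against 0.57 and 0.59 for Dox 2 and 3. Whether such a weaker response, if there was one, came from less knockdown was not tested, because the targeted gene was not analysed here.

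The doxycycline effect differed between shBRaf and shGFP for 1106 genes, and 10 of 100 drawn splits of both lines' arrays gave at least as many, the highest 2108, so chance cannot be excluded for this count. These splits are no pure measure of chance, because 11 of the 99 others kept the real shBRaf groups and with them its doxycycline change. Of those 11, 6 gave as many, the highest among them. Of the 88 that regrouped shBRaf, 3 gave as many, at most 1503. Each of these 3 set Dox 1 of shBRaf with 2 of its Control arrays, apart from Dox 2 and Dox 3. These 3 thus kept part of the doxycycline change, so the share of splits does not measure chance. The splits of both lines also leave aside the replicate number that the lines share. For doxycycline in shBRaf itself the real split gave 3036 genes and the highest of the others 1777, with 1 of 10 splits at the real count, and 10 splits are too few for a share under 0.05. The other splits above 0, at 959, 1109 and 1777, set Dox 1 with 2 Control arrays and kept Dox 2 and Dox 3 together. Each split that parted Dox 2 from Dox 3 gave 0. The differences were −1.21 for DUSP6, −2.13 for SPRY4, 3.67 for MATN2, 3.55 for SPP1, 3.36 for MGP, −4.40 for CXCL8, −3.58 for TMEM158 and −3.55 for SOX8. Without 1 array at a time, the SPRY4 difference kept its call in 5 of 12 fits, with values of −2.97 to −1.66.

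Between sh2BRaf and shGFP the doxycycline effect differed for 2579 genes, by −0.68 for DUSP6, −4.14 for SPRY4, −1.75 for ETV5, −1.32 for CCND1, 1.32 for MITF, 6.34 for TAC1, 6.27 for MGP, 6.12 for HPGD, −5.12 for CXCL8, and −4.62 for both SIRPB1 and MIR100HG. Without 1 array at a time, the MITF difference lost its call in all 10 fits (1.25 to 1.38), and those of CCND1 and DUSP6 kept theirs in 3 and 4 of 10. Between shBRaf and sh2BRaf it differed for 1281 genes, by 1.38 for ETV5, 3.54 for PDE9A, 3.01 for ITGA9, 2.77 for ACSF2, −7.25 for TAC1, −4.78 for NIBAN1 and −3.72 for DMD. The shBRaf Control arrays varied widely for TAC1 (1604 ± 1247, SD) and NIBAN1 (2648 ± 1729), and PDE9A had 1 of 2 bright probe sets in that direction. DMD had 2 of 3 and was at 14.5 ± 11.5 (SD) in sh2BRaf Control, close to background. Part of the TAC1 difference between sh2BRaf and shGFP lay in shGFP.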

How the results depend on the processing

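Tests chosen only after the result was seen were the fits without the Control and Dox arrays numbered 1 of shGFP and shBRaf and the block within sh2BRaf for DMSO. Across 861 values of named genes, 816 of them past the threshold, quantile normalization kept 98.77% of calls with their direction and centring each array on its median 99.39%, and both left each of the 17 counts of genes, and the count of list calls, within 1.5 times. The shares kept were 97.06% with no filter on dim probe sets, 99.88% with the filter at the 60th percentile, 99.26 and 99.63% with pseudocounts of 1 and 64, 97.55% with every probe set on its own, 96.69% for eBayes without trend, 86.4% for only the groups compared, 82.72% for the mean of all probe sets and 89.02% over the fits without 1 array. Where leaving out 1 array left a group with 1, that array was assumed to vary like the other groups. Signal close to background limits the fold changes of dim genes, since 21.61 to 22.82% of an array's probe sets lay under 16. Where nothing else is said, the cause was not tested.

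Counts rose with every probe set on its own, by its construction, since more features were tested: to 4837 for doxycycline in shBRaf, 6044 in sh2BRaf and 2 in shGFP, 3873 for sh2BRaf minus shGFP, 7404 and 11562 for A375control_1677 and A375control_B439006, 9526 and 5881 for A375sh2BRaf_1677 and A375sh2BRaf_B439006. It gave 13639 and 12855 for the direct differences of the compounds in A375control and sh2BRaf, 9713 and 10059 for sh2BRaf minus A375control in the effects of A375sh2BRaf_1677 and A375control_1677 and of the B439006 groups, 7658 for AR341787 and 8101 for doxycycline minus A375sh2BRaf_1677. A minimum log2 change of 1 lowered them by its construction, in the same order to 633, 1270, 0, 1141, 1584, 2548, 1896, 1305, 3532, 3283, 3321, 3392, 1608 and 2585, with 369 for shBRaf minus shGFP and 511 for shBRaf minus sh2BRaf.

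With only the groups compared in the fit, counts were 8 for doxycycline in shBRaf, 6668 in sh2BRaf, 0 in shGFP, 26 for shBRaf minus shGFP, 278 for shBRaf minus sh2BRaf, 7066 for A375control_1677 and 5872 for A375sh2BRaf_B439006. This fit takes its spread from those arrays alone, shBRaf Dox 1 among them. Without the Control and Dox arrays numbered 1 of shGFP and shBRaf they were 5093, 804 in shGFP, 3503 for shBRaf minus shGFP, 4214 for sh2BRaf minus shGFP and 2847 for shBRaf minus sh2BRaf. For doxycycline in shGFP, no filter gave 2, and the mean of all probe sets and eBayes without trend gave 0. The mean of all probe sets gave 750 for shBRaf minus sh2BRaf, and a pseudocount of 1 gave 1 for DMSO in sh2BRaf. An estimated correlation in camera gave 2 list calls against 76.

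Leaving out 1 array at a time gave 2021 to 4402 genes for doxycycline in shBRaf, 2410 to 2574 in sh2BRaf, 0 to 86 in shGFP, 541 to 2868 for shBRaf minus shGFP, 1639 to 2549 for sh2BRaf minus shGFP, 543 to 1891 for shBRaf minus sh2BRaf, 2483 to 2598 for A375sh2BRaf_B439006, 1760 to 4803 for AR341787 and 1 to 4 for DMSO in sh2BRaf. The highest counts came without shBRaf Dox 1 (4402, 2868 and 1891), shGFP Control 1 (86 and 4803) and sh2BRaf DMSO 2 (4 for DMSO), and some of the lowest without shBRaf Dox 2 (2021 and 541), sh2BRaf Control 2 (2410, 543), sh2BRaf Dox 1 (1639) and sh2BRaf DMSO 1 (2483). The list calls numbered 72 to 85, the latter without shBRaf Dox 1, and the other counts stayed within 1.5 times.

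The replicate number as a block gave 3289 genes for doxycycline in shBRaf, 3984 in sh2BRaf and 0 in shGFP, 1289 for shBRaf minus shGFP and 4889 for A375control_1677, and of its 15 counts the shGFP one moved by more than 1.5 times. Deviations of same-numbered Control and Dox arrays correlated at 0.03, 0.15 and 0.03 in shBRaf and 0.32, 0.11 and 0.06 in shGFP. The highest correlations with another number were 0.03, −0.07 and 0.03 in shBRaf and −0.18, 0.14 and 0.08 in shGFP. As a hint from the data, number 1 of shGFP and number 2 of shBRaf were thus closest to their own number, and the others were not. Across probe sets shGFP Control 1 correlated at 0.985 with shGFP Dox 1, against 0.968 and 0.971 with Control 2 and 3. In groups of 2 the deviations of same-numbered arrays correlated at −0.05 to 0.08. Between the lines, same-numbered Control arrays of shGFP and shBRaf correlated at 0.43, 0.12 and 0.16 and Dox arrays at 0.01, −0.04 and 0.00, so that a number shared something between the Control arrays, with Control 2 of shGFP closer to another number (0.19). That block holds DMSO and Control in separate sets, and a replicate block within sh2BRaf on these 4 arrays gave 0 genes for DMSO with limma. The fit for AR341787 held a term for the line, but no block by replicate number was run, because its 1 array a line carries no number.

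Profile correlations moved by more than the spread between single arrays as follows. That spread was an SD of 0.19 and 0.18 for doxycycline in shBRaf with doxycycline in sh2BRaf and with A375control_1677, too wide for small moves to count, and at most 0.03 for the other pairs. For doxycycline in sh2BRaf with A375sh2BRaf_1677, r was 0.15 with the mean of all probe sets, 0.10 with every probe set on its own, 0.14 with a pseudocount of 64 and 0.10 to 0.13 without 1 array. With A375sh2BRaf_B439006 it was 0.46 with no filter, 0.54 at the 60th percentile, 0.49 with the mean, 0.51 with every probe set, 0.47 and 0.54 with pseudocounts of 1 and 64, and 0.48 to 0.49 without 1 array. For doxycycline in shBRaf with A375control_B439006 it was 0.20 at the 60th percentile, 0.23 with the mean, 0.15 and 0.21 with pseudocounts of 1 and 64, and 0.13 to 0.20 without 1 array. For A375control_1677 with A375sh2BRaf_1677 it was 0.02 with the mean, −0.03 with every probe set and 0.00 with a pseudocount of 64, and for the B439006 groups 0.09 with the mean. Across the labels, A375control_1677 with A375sh2BRaf_B439006 gave 0.67 with no filter, 0.78 at the 60th percentile, 0.71 with every probe set, 0.66 and 0.78 with pseudocounts of 1 and 64, and 0.68 to 0.71 without 1 array. A375control_B439006 with A375sh2BRaf_1677 gave 0.71, 0.81, 0.72 with the mean, 0.71 and 0.81 in the same settings, and 0.71 to 0.75 without 1 array.

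Directions reversed in 23 cases, each with the mean of all probe sets of a gene. These were WDR12 at 0.09 for doxycycline in shBRaf, ERBB2 at −0.12 and WDR12 at 0.06 for shBRaf minus shGFP, and HBB at 0.14 for AR341787. For A375control_B439006 they were RAB27A at −0.11, ERBB3 at 0.11, MDM2 at 0.21 and NPM1 at 0.06, and for A375sh2BRaf_1677 RAB27A at −0.32, CD44 at 0.25 and MDM2 at 0.52. In the direct differences of the compounds RAB27A stood at 0.33, CD44 at −0.14 and MDM2 at −0.14 in A375control and MDM2 at 0.30 in sh2BRaf. In the line difference of the B439006 groups ERBB3 stood at −0.06, CD44 at −0.01 and NPM1 at −0.07. For doxycycline minus A375sh2BRaf_1677 DUSP4 stood at 1.55, RAB27A at 0.25, CD44 at −0.29, BCL2L11 at −0.19 and WDR12 at 0.55.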

Other observations

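The gene families and their genes in this part were chosen after their values were seen, and no test of an explanation was run on them. Of 29 replication-dependent histone genes, whose transcripts normally end without a poly(A) tail, 11 were higher and 0 lower with doxycycline in shBRaf, 13 and 0 in sh2BRaf (median log2 change 1.25) and 0 and 0 in shGFP (−0.17) in limma's test, with the same direction after quantile normalization and after centring each array on its median. H2AC6 rose by 4.61 ± 0.60, H2BC12 by 3.85 and H1-2 by 3.17 with doxycycline in sh2BRaf, and by 1.76, 1.69 and 1.95 in shBRaf. The doxycycline effect differed from that in shGFP for 6 of these genes in shBRaf and 12 in sh2BRaf, all more positive. With AR341787 9 were higher and 1 lower (median 1.07), and 9 were higher for A375control_B439006, 14 for A375sh2BRaf_1677 and 8 for A375sh2BRaf_B439006, with 0 lower, against 2 higher and 1 lower for A375control_1677, with the same direction under both scalings.

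Of 21 HLA genes, which present antigens, 10 were higher and 0 lower with doxycycline in sh2BRaf, 13 and 0 for A375control_1677, 10 and 0 for A375control_B439006, 8 and 0 for A375sh2BRaf_1677, 7 and 0 for A375sh2BRaf_B439006 and 12 and 0 for AR341787, with the same direction under both scalings. Doxycycline gave 6 higher and 2 lower in shBRaf and 0 of either in shGFP in limma's test, under both scalings as well.

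Of 436 genes named ZNF, which encode zinc finger proteins, 187 were lower and 42 higher for A375control_B439006 and 177 lower and 35 higher for A375sh2BRaf_1677. Lower genes numbered 184 and 171 after quantile normalization and 198 and 184 after centring each array on its median. The 57 cytosolic ribosomal protein genes had 43 and 44 lower in these comparisons as deposited but 10 and 3 after quantile normalization, so no direction is given for them. Of 7 metallothionein genes 4 and 2 were higher, and 3 and 1 after quantile normalization.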
